A study of Mus musculus with 34 samples.

How the data were processed

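RNA was measured by sequencing of poly(A)-selected, strand-specific libraries from mouse colon tumour organoids, per the labels' protocols. The deposited table gave expected counts per gene, which the authors obtained with Salmon 1.3.0 on genome build mm10, per the submitters' processing notes. The deposited values were whole numbers and were not scaled between libraries. How transcripts were summed to genes and which annotation release was used were not stated. The table held 54354 genes, of which 29742 had 0 counts in every library. Gene positions were taken from GENCODE M21, on the same build, which held 51528 of the IDs and lacked 2826. Where a gene name occurred more than once, the entry with the most counts kept the plain name, and 1243 entries without a name held at most 0.0475% of the counts of any library.

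Total counts per library ranged from 883253 to 6597099. Samples were grouped as labelled. Replicate numbers did not pair libraries between groups, with correlations from -0.069 to 0.076 after removing group means, so the main fits had no block. Libraries with neighbouring numbers resembled one another within a group, and runs were defined from this after the values had been seen: shControl replicates 1 to 4, 5 to 7 and 8 to 10, clone1 replicates 1 to 6 and 7 to 9, and clone2 replicates 1 to 2, 3 to 6 and 7 to 9. The resemblance was weakest in clone1, with a median r of -0.033 within runs and -0.161 between them, and clone1 replicate 3 lay nearest replicate 9. The labels name no sequencing batch.

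All comparisons, lists, tests and rules for naming genes were fixed before the data were examined, except where stated. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), normalised by TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 21 libraries of the knockout experiment shared 1 fit, the 13 of the hairpin experiment another, and the difference between both effects came from a fit of all 34. The fits had a common biological coefficient of variation of 0.218, 0.281 and 0.248. Levels are TMM-normalised CPM, counts relative to the effective library total, computed here. The intervals cover the fitted spread between libraries alone. From 34 gene lists with 721 genes, lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. Members were counted as past the threshold over all genes tested, and adjusted over the list alone where stated. Lists were written from general knowledge, and some genes stand in more than 1 list, such as Pla2g2a.

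Genes were named by rule: Degs1, Yap1 and 7 marker genes always, the 5 largest rises and 5 largest falls past the threshold with a mean log2 CPM of at least 3, leaving out symbols of the forms used for predicted genes and pseudogenes, and up to 4 members of each described list with a mean log2 CPM of at least 1. GENCODE M21 types Pla2g2a as a polymorphic pseudogene, and it stayed in since the rule went by symbol. A few of the genes that this rule selected are not reported here. The hair-type keratins as a set and the genes by chromosome were chosen after their values were seen.

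The steps were tested on simulated data with 200 genes changed by known amounts. In the simulated knockout experiment of 11514 genes, shares cover only the changed genes that still passed the filter on low counts. Those were 38 lowered and 50 raised by a log2 fold of 2, and 40 lowered and 50 raised by 1. Of those lowered and raised by 2, 94.7% and 92% were called with the right sign. Of those changed by 1 in either direction, 60% were. Unchanged genes made up 2.86% of those calls. In the simulated hairpin experiment of 11094 genes, the shares were 75.5% and 91.8% for 2, and 30.6% and 62% for 1, and unchanged genes made up 7.25% of calls. Simulated libraries were drawn independently, without the runs seen in the data, so these shares do not cover that structure.

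Alternatives were size factors as in DESeq2, no filter on low counts, the Wald test of DESeq2 1.42.0, a threshold of 0.01, 1 fit of all groups, only the compared groups in a fit, the replicate number as a block, leaving out each replicate of groups with 3, and subsets of shControl by library number. Chosen after seeing the data were shControl replicates 8 to 10 alone, knockout replicates 7 to 9 or 1 to 6 alone, leaving out the shallowest library, limma with and without the run as a random block, and shControl in place of Scrambled. Each count of genes was also compared with 100 drawn splits of the libraries.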

Results

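Polyadenylated RNA was sequenced in 34 libraries of mouse colon tumour organoids, 3-dimensional epithelial cultures whose genotype was given as AKP. A hairpin experiment comprised 10 libraries with a control hairpin (shControl) and 3 with a hairpin against Yap1 (shYAP). A CRISPR experiment comprised 3 libraries of a Scrambled control and 9 libraries of each of 2 Degs1 knockout clones. The labels did not say whether replicates were separate cultures, and the Scrambled control and each clone were 1 line each, so n counts libraries. Library totals ran from 883253 to 6597099 counts. The shallowest were clone1 replicate 2 at 883253 and shControl replicate 3 at 1747533, and every other library held at least 2470845. Each library resembled a library of its own group most closely, with Pearson r across genes from 0.914 to 0.974, where genes are not independent replicates. All p-values set a difference against the spread between these libraries, which may be technical. Fold changes are log2 values with their standard error.

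Degs1 encodes the desaturase that turns dihydroceramide into ceramide, the last step of de novo ceramide synthesis. Degs1 (ENSMUSG00000038633, chromosome 1, 182275772 to 182282804, mm10) averaged 7.72 ± 2.62 CPM (counts relative to the library total, SD, n = 3) in Scrambled, 2.41 ± 1.32 (n = 9) in clone1 and 1.71 ± 0.892 (n = 9) in clone2. All 18 knockout libraries lay below the lowest Scrambled library, at 4.94 CPM. Residual Degs1 reads ranged from 1 to 27 counts in clone1 and from 1 to 14 in clone2, and where the edit lies was not stated, so mRNA does not measure the loss of protein. In the hairpin experiment Degs1 averaged 5.22 ± 1.67 CPM (n = 10) in shControl and 14.7 ± 4.21 (n = 3) in the libraries labelled shYAP. The shControl libraries ranged from 2.63 to 7.92 CPM and overlapped both clones, which reached 4.58 and 2.86. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596) encodes the transcriptional coactivator of the Hippo pathway. It averaged 16.5 ± 4.13 CPM in shControl and 19.04 ± 1.12 in the libraries labelled shYAP, a change of 0.20 ± 0.23 (edgeR adjusted p = 0.619) with a 95% confidence interval from -0.30 to 0.69. Yap1 mRNA therefore went against that label, and every direction drawn from it refers to the libraries labelled shYAP and not to a measured loss of Yap1. Yap1 in Scrambled, clone1 and clone2 averaged 14.8 ± 3.11, 14.5 ± 1.60 and 18.5 ± 5.58 CPM.

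**Figure D1:**
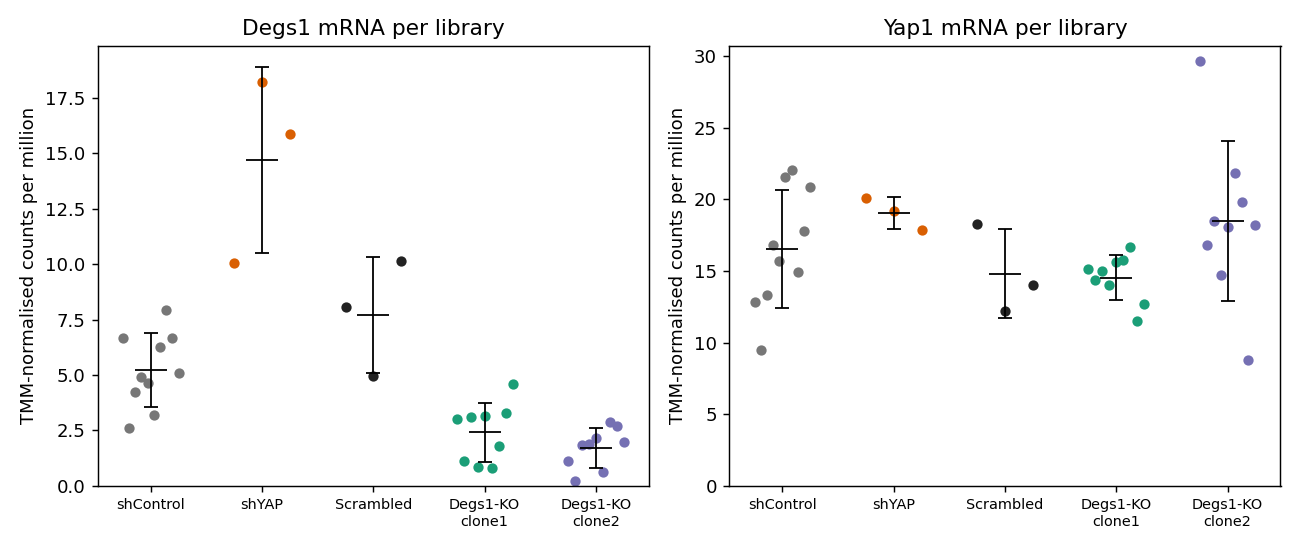
TMM-normalised CPM of Degs1 (left) and Yap1 (right) in each library, with bars at the group mean and SD. All 18 knockout libraries lie below the lowest Scrambled library in Degs1, and the 3 libraries labelled shYAP, from 17.9 to 20.1, lie inside the shControl range of 9.49 to 22.04 in Yap1. In Degs1 the shControl range of 2.63 to 7.92 overlaps the knockout libraries.

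The first comparison asked what both Degs1 knockout clones, weighted equally, had changed against Scrambled. Car9, a carbonic anhydrase induced by hypoxia, fell by 4.86 ± 0.17 on the log2 scale (edgeR adjusted p = 1.19e-23), from 124 ± 4.24 CPM in Scrambled (n = 3) to 13.5 ± 3.57 in clone1 (n = 9) and 1.36 ± 0.809 in clone2 (n = 9). The libraries labelled shYAP, without a Degs1 knockout, also had low Car9, at 11.1 to 13.5 CPM. The secreted phospholipase Pla2g2a fell by 4.04 ± 0.17 (adjusted p = 1.62e-20) and the stem cell receptor Lgr5 by 2.66 ± 0.25 (adjusted p = 2.72e-10). Pid1, an adaptor that dampens insulin signalling, rose by 4.38 ± 0.32 (adjusted p = 7.89e-12), and the basal keratin Krt15 by 4.01 ± 0.36 (adjusted p = 1.11e-09). Degs1 itself fell by 1.86 ± 0.38 (adjusted p = 4.81e-04). In all, 2027 of 11514 tested genes passed, 966 higher and 1061 lower, and 673 of them changed by at least 1 on the log2 scale. Without Scrambled replicate 1 or 2, 1254 or 1208 genes passed. Limma called 2192 genes, and 1063 with the run of libraries as a random block, 380 higher and 683 lower.

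The other large rises were the hair-type keratins Krt32 (3.88 ± 0.73) and Krt31 (3.76 ± 0.38) and the fatty acid carrier Fabp4 (3.76 ± 0.43). Krt32 passed in neither limma fit, at 3.65 with the run as a random block (adjusted p = 0.122) and 3.67 without it (adjusted p = 0.0509). Keratin paralogs share sequence, so the assignment of reads among them is uncertain. As a set chosen after its values were seen, 11 hair-type keratins summed to 42.9 ± 5.48 CPM in Scrambled, 233 ± 52.9 in clone1, 494 ± 126 in clone2, 128 ± 97.2 in shControl and 234 ± 26.5 in the libraries labelled shYAP. The other large falls were the glycosyltransferase Mgat4c (-3.42 ± 0.30) and the collagen receptor subunit Itga2 (-2.85 ± 0.20). Of the marker genes fixed in advance, Clu, the marker of revival stem cells, fell by 1.53 ± 0.34 (adjusted p = 0.00112). Anxa1 (0.50 ± 0.18, adjusted p = 0.0614), Ly6a (0.30 ± 0.14, adjusted p = 0.148) and Yap1 (0.14 ± 0.21, adjusted p = 0.699) did not pass. Anxa1 did pass with DESeq2 (0.51, adjusted p = 0.0139), with the replicate number as a block (0.47), with replicates 7 to 9 (0.19) or 1 to 6 (0.64) alone and against shControl (0.69), and Ly6a with replicates 1 to 6 alone (0.44) and against shControl (0.73). The YAP-responsive matricellular gene Ccn2 fell by 1.61 ± 0.23 (adjusted p = 2.79e-06). Ccn1 had a value of -0.93 ± 0.29 (adjusted p = 0.0213), and was no longer past the threshold without Scrambled replicate 1 (-0.85) or replicate 2 (-0.74). Olfm4 had 2 counts in shControl and 0 in every other group and was not tested.

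**Figure D2:**
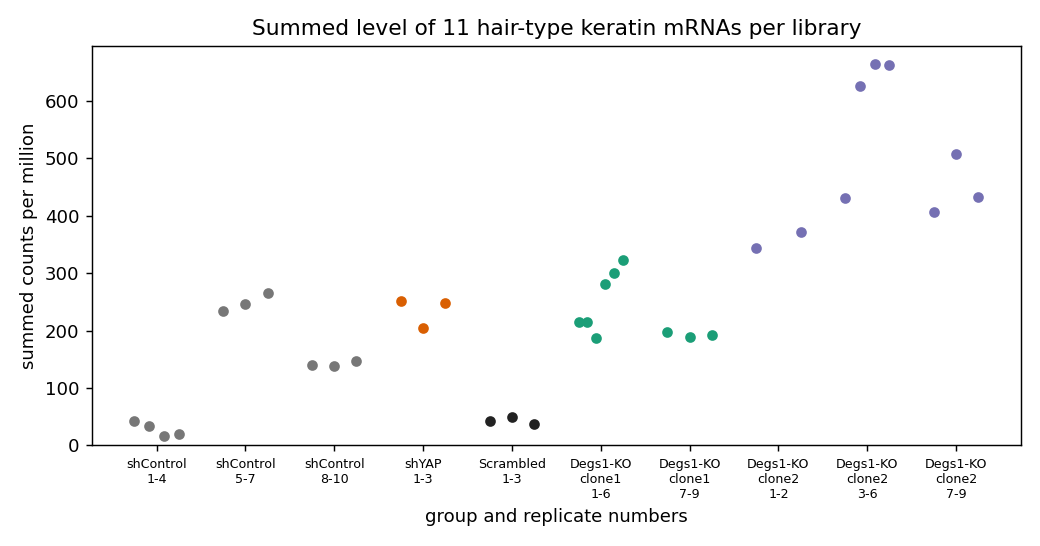
Summed CPM of 11 hair-type keratin mRNAs in each library, by group and run of replicate numbers, 1 point per library. All 9 clone2 libraries lie above the highest shControl library at 264.5, and 3 of 9 clone1 libraries do.

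Of 24 genes of G2 and mitosis, 22 were lower and 0 higher, among them Ccnb2 (-0.99 ± 0.14), Ccna2 (-1.02 ± 0.17), Plk1 (-1.005 ± 0.194) and the kinesin Cenpe (-1.09 ± 0.22), and the list passed camera (adjusted p = 2.37e-14) and kept the call with an estimated correlation (0.0157). Adjusted over the list alone, 23 were lower. Of 24 S phase genes, 13 were lower, 1 was higher and 10 did not pass, with the helicase subunits Mcm3 (-1.19 ± 0.18) and Mcm6 (-1.19 ± 0.20) among the lower. That list's camera call (adjusted p = 1.51e-07) was lost at adjusted p = 0.380 with an estimated correlation. The Paneth and deep crypt secretory list, with 6 genes tested, had 2 lower, Pla2g2a and the matrix protease Mmp7 (-1.73 ± 0.16), and 1 higher, and held with an estimated correlation (adjusted p = 0.00151). The crypt-base stem cell list had 8 of 18 genes lower and 1 higher, with Lrig1 (-1.42 ± 0.21) beside Lgr5, and held as well (adjusted p = 0.00367). With shControl libraries in place of Scrambled this list no longer passed (camera p = 0.608), and Lgr5 in clone1 changed sign. The goblet cell list had 2 of 8 lower, including Klk1 (-2.11 ± 0.36), with a call (adjusted p = 0.0449) that was lost at adjusted p = 0.174 with an estimated correlation and on leaving out any 1 Scrambled library (camera p from 0.0145 to 0.0289).

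Of 24 genes of the integrated stress response, 12 were lower, 1 was higher and 11 did not pass, including the cytokine Gdf15 (-1.97 ± 0.23) and the serine and folate enzymes Psph (-1.45 ± 0.19) and Mthfd2 (-1.39 ± 0.23). The list's call (camera adjusted p = 2.31e-07) rose to adjusted p = 0.05004 with an estimated correlation, at the threshold and not past it. Of 19 endoplasmic reticulum chaperones tested, 7 were lower and 0 higher, and 14 were lower adjusted over the list alone, with Sdf2l1 (-1.10 ± 0.24), Hspa5 (-0.94 ± 0.11), Creld2 (-0.87 ± 0.19) and Manf (-0.77 ± 0.13) as examples. Their call (adjusted p = 7.26e-05) was lost at adjusted p = 0.147 with an estimated correlation. Of 17 YAP/TAZ-TEAD targets, 4 were lower and 0 higher, Ccn1, Ccn2, the tissue factor gene F3 (-1.75 ± 0.21) and Myof (-0.58 ± 0.14). Taken clone by clone, 0 of the 17 passed as lower in both clones, and 1 passed in both with opposite signs. The list's call (camera adjusted p = 0.0147) was lost at adjusted p = 0.154 with an estimated correlation. It was also lost without Scrambled replicate 2 (camera p = 0.0127, not past the threshold after adjustment), and Myof stood at -0.03 against shControl. Of 13 mitochondrially encoded mRNAs, 7 were higher and 0 lower, with mt-Atp6 at 0.82 ± 0.11 and mt-Co1 at 0.94 ± 0.19, though nuclear copies of mitochondrial sequence make their assignment uncertain. The list's call (adjusted p = 5.87e-05) was lost at adjusted p = 0.159 with an estimated correlation, and against shControl (camera p = 0.377).

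No other list passed in this comparison. The revival and fetal-like list had 3 of 22 genes higher and 7 lower, and its median (0.02), mean (-0.19) and test (down, camera adjusted p = 0.566) differed in sign. De novo sphingolipid synthesis had 1 of 13 genes lower, Degs1, and 1 higher, Cers5 (0.62 ± 0.22, not past the threshold without Scrambled replicate 1 at 0.51 or replicate 3 at 0.57). Ceramide use and breakdown had 1 of 23 higher and 3 lower, and cholesterol synthesis 8 of 25 higher and 2 lower, with a camera adjusted p of 0.785 and 0.455. Of 22 hypoxia and glycolysis genes, 2 were higher and 4 lower, with a median of 0.03, a mean of -0.22 and a camera adjusted p of 0.0961.

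Each clone was then set against Scrambled alone. In clone1 (n = 9), 1459 genes passed, 686 higher and 773 lower, and 804 or 779 passed without Scrambled replicate 1 or 2. Limma called 1512 genes in clone1, and 497 with the run as a random block. The colonocyte hydroxylase Cyp2c55 rose by 3.78 ± 0.56 (edgeR adjusted p = 1.37e-04), carbonic anhydrase Car1 by 2.96 ± 0.49 and the differentiation keratin Krt20 by 1.95 ± 0.41, and 9 of 16 absorptive colonocyte genes were higher with 0 lower. That list's call (camera adjusted p = 6.93e-07) was lost at adjusted p = 0.0877 with an estimated correlation. The calprotectin subunit S100a8 rose by 3.46 ± 0.48, from 15.03 ± 2.60 to 165 ± 44.7 CPM. The homeobox gene Hoxb7 (-4.82 ± 0.29), the mitochondrial genes Decr1 (-3.92 ± 0.27) and Fundc2 (-3.39 ± 0.14) and the purine enzyme Gmpr (-3.50 ± 0.64) were the largest falls beside Pla2g2a. Degs1 in clone1 fell by 1.57 ± 0.43 (adjusted p = 0.0117), and did not pass without Scrambled replicate 1 (-1.55) or replicate 3 (-1.34). Of the 10 lists that passed camera in clone1, 1 held with an estimated correlation, the Paneth list (adjusted p = 0.00456). Lgr5 had a value of -1.03 ± 0.28 (adjusted p = 0.0104), did not pass without Scrambled replicate 1 (-0.97) or replicate 3 (-0.96), and was 0.58 against shControl.

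In clone2 (n = 9), 3810 genes passed, 1902 higher and 1908 lower. Limma called 4067 genes in clone2, and 2522 with the run as a random block. The peroxisomal receptor-like gene Pex5l rose by 6.03 ± 0.93 (edgeR adjusted p = 5.41e-05), the small heat shock gene Hspb8 by 5.37 ± 0.51 from 6 counts over 3 Scrambled libraries, Dapl1 by 5.10 ± 0.56, Pid1 by 5.07 ± 0.33 and Samt1b by 4.97 ± 0.40. Car9 fell by 6.53 ± 0.22, Itga2 by 5.01 ± 0.25, the NAD hydrolase Cd38 by 4.50 ± 0.24 and Lgr5 by 4.30 ± 0.31. Absorptive colonocyte genes went the other way from clone1, with 8 of 16 lower, including Lypd8 (-3.37 ± 0.34) and Muc13 (-2.55 ± 0.33), and 2 higher, and a call (camera adjusted p = 0.0173) lost at adjusted p = 0.395 with an estimated correlation. Of 24 S phase genes 20 were lower, Mcm5 at -1.87 ± 0.28, and all 24 genes of G2 and mitosis were lower. The latter list held with an estimated correlation (adjusted p = 0.0260) and the former was lost at adjusted p = 0.244 with an estimated correlation. Of 17 YAP/TAZ-TEAD targets 7 were lower and 0 higher, Ccn2 at -2.72 ± 0.27 and F3 at -2.85 ± 0.24, with a call (adjusted p = 0.00221) lost at adjusted p = 0.0821 with an estimated correlation. Wnt/beta-catenin targets had 7 of 16 higher, including Apcdd1 (3.43 ± 0.46) and Bambi (2.77 ± 0.32), and 2 lower. Apcdd1 and Bambi lie on chromosome 18, whose genes had a median of 0.54 in clone2, below either rise. The Wnt/beta-catenin list's call (adjusted p = 0.00935) was lost at adjusted p = 0.370 with an estimated correlation, and its direction reversed against shControl (camera p = 0.828).

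The clones shared 678 genes past the threshold with the same sign, 334 higher and 344 lower, and 139 genes had opposite signs. Krt15 (3.77 ± 0.37 in clone1 and 4.24 ± 0.37 in clone2), Fabp4 (3.94 ± 0.44 and 3.57 ± 0.43) and mt-Atp6 (0.85 ± 0.11 and 0.80 ± 0.11) rose in both. In both, lower values were measured for Pla2g2a (-3.56 ± 0.21 and -4.51 ± 0.21), Mmp7 (-1.90 ± 0.19 and -1.55 ± 0.18), Ccnb2 (-0.94 ± 0.15 and -1.04 ± 0.15) and Clu (-1.47 ± 0.38 and -1.60 ± 0.38). Among the fixed lists, 7 genes each of the integrated stress response and of G2 and mitosis were lower in both clones. So were 4 each of the endoplasmic reticulum chaperones, S phase, hypoxia and glycolysis and the crypt-base stem cell list. Higher in both were 5 mitochondrially encoded mRNAs, and 6 absorptive colonocyte genes had opposite signs. Of the YAP/TAZ-TEAD targets, 0 passed in both with the same sign. Both comparisons used the same 3 Scrambled libraries, so part of the sharing may come from them. Over the genes tested, the fold changes of both clones had a covariance of 0.306 and a Pearson r of 0.413, against a mean covariance of 0.0846 and a mean r of 0.753 in 20 simulations of unchanged groups with shared controls, where genes are not independent replicates. Leaving out Scrambled replicate 1 or 2 brought the shared count to 365 or 359. It was 241 in limma with the run as a random block and 709 without that block, and 1048 with knockout replicates 1 to 6 alone.

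**Figure D3:**
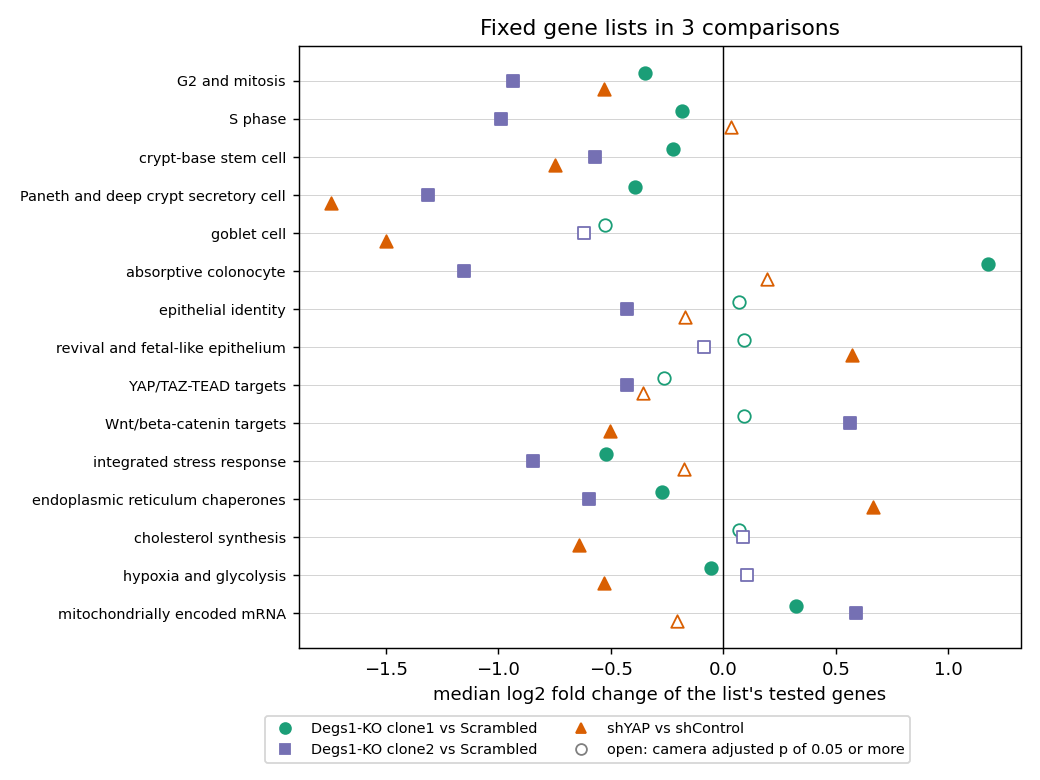
Median log2 fold change (horizontal axis) of the tested genes of 15 fixed lists in clone1, clone2 and the libraries labelled shYAP, each against its control. Filled symbols passed camera at the preset correlation, and the absorptive colonocyte medians lie at 1.17 in clone1 and -1.15 in clone2.

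Setting clone2 against clone1 asked how far 2 knockouts of the same gene differed. Among genes with a mean log2 CPM of at least 3, the largest falls in clone2 were those of Cyp2c55 (-6.14 ± 0.43, edgeR adjusted p = 6.79e-10), the glucuronosyltransferase Ugt2b34 (-5.28 ± 0.33), the proton channel Otop1 (-5.07 ± 0.28), Tm4sf20 (-5.05 ± 0.24) and the efflux pump Abcb1a (-4.79 ± 0.16), at 115 ± 14.04 CPM in clone1 and 4.24 ± 1.78 in clone2 (n = 9 each). Higher in clone2 were Pex5l (5.75 ± 0.58), Hspb8 (5.46 ± 0.34), Hoxb7 (4.86 ± 0.25), the cornified envelope gene Sprr2a1 (4.72 ± 0.60) and Samt1b (4.67 ± 0.25). Sprr2a1 belongs to a family of near-identical paralogs, and ranged from 44.9 to 1675 CPM within clone2. In all 5649 genes differed, 2717 higher and 2932 lower. That was more than in either clone against Scrambled, where the control had 3 libraries and not 9. Degs1 did not differ detectably (-0.58 ± 0.37, adjusted p = 0.191).

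Of 16 absorptive colonocyte genes 12 were lower in clone2, including Muc13 (-4.20 ± 0.28), Krt20 (-3.73 ± 0.31) and Muc3 (-3.66 ± 0.49), and 1 was higher, with a list median of -3.18. The epithelial identity list had 11 of 22 lower and 3 higher, with the transcription factors Gata6 (-1.82 ± 0.47) and Cdx2 (-1.55 ± 0.31) and the keratin Krt8 (-1.51 ± 0.09) among the lower. Within replicates 7 to 9 alone, Gata6 had -0.79 and did not pass (adjusted p = 0.264). Of 24 S phase genes 20 were lower, Mcm7 at -1.54 ± 0.13, and of 17 YAP/TAZ-TEAD targets 7 were lower, with Crim1 at -3.14 ± 0.24 and Ccn2 at -2.23 ± 0.22. Lgr5 fell by 3.27 ± 0.28 and Car9 fell by 3.35 ± 0.22, and the Wnt/beta-catenin antagonist gene Apcdd1 rose by 3.18 ± 0.29. In this comparison 10 lists passed camera and 0 with an estimated correlation, where the absorptive and epithelial identity lists both stood at adjusted p = 0.169 with an estimated correlation, S phase at adjusted p = 0.563 with an estimated correlation and the YAP/TAZ-TEAD targets at adjusted p = 0.237 with an estimated correlation. Within replicates 7 to 9 of both clones, a separate run in each, 4748 genes differed. With the same replicates against Scrambled, 1759 genes passed in clone1 and 4183 in clone2, at n = 3 per group.

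By chromosome, grouped after the values were seen, genes of chromosome 18 had a median of 0.54 in clone2 against Scrambled, from 0.45 to 0.59 over its 9 libraries, and from -0.01 to 0.10 in clone1. Genes of chromosomes 4 and 9 had medians from -0.27 to -0.20 in every clone1 library.

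**Figure D4:**
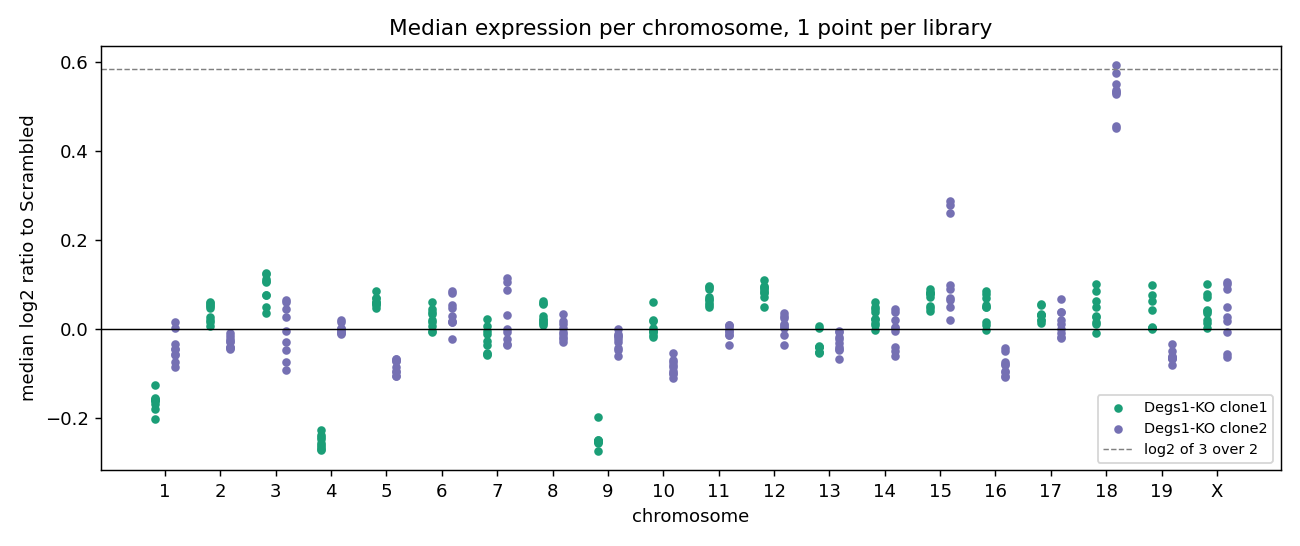
Median log2 ratio to Scrambled of the genes of each chromosome (horizontal axis), 1 point per knockout library. Chromosome 18 lies at 0.45 to 0.59 in clone2, near the dashed line at 0.58, the log2 of 3 over 2.

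The hairpin experiment compared the 3 libraries labelled shYAP with 10 shControl libraries, in which Yap1 mRNA did not differ. Bex1 fell by 5.22 ± 0.53 (edgeR adjusted p = 1.71e-06), to 4 counts over the 3 libraries labelled shYAP. The intestinal homeobox gene Prox1 (-4.62 ± 0.51), the mitochondrial carrier Slc25a4 (-4.58 ± 0.33), Zfp422 (-4.43 ± 0.42) and Alb (-4.34 ± 0.55) fell almost as far. Slc25a4 averaged 74.1 ± 20.9 CPM in shControl (n = 10) and 3.10 ± 0.798 in the libraries labelled shYAP (n = 3). Higher were the heat shock gene Hspb1 (3.06 ± 0.54), Trbc1 (2.61 ± 0.23), Tmem40 (2.50 ± 0.31), the growth factor Bmp4 (2.48 ± 0.26) and Khdc1a (2.44 ± 0.20). In all 1261 of 11094 tested genes passed, 607 higher and 654 lower. Of those changed by at least 1 on the log2 scale, 179 were higher and 412 lower.

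Revival and fetal-like genes were higher in the libraries labelled shYAP, 13 of 22 with 0 lower, and 15 higher and 1 lower adjusted over the list alone. Clu rose by 1.92 ± 0.25 (adjusted p = 4.58e-05), from 10.9 ± 3.91 to 42.1 ± 3.29 CPM, Sprr1a by 1.71 ± 0.29, Ly6a by 0.93 ± 0.13 and Anxa1 by 0.73 ± 0.15. The list passed camera (adjusted p = 6.94e-11) and was at the threshold, barely past it, with an estimated correlation (adjusted p = 0.04999). Degs1 rose by 1.47 ± 0.29 (adjusted p = 0.00205), the only sphingolipid synthesis gene past the threshold, and the glucosylceramide synthase Ugcg fell by 1.84 ± 0.26. The sphingolipid list's call (adjusted p = 0.0314) was lost at adjusted p = 0.321 with an estimated correlation and without shYAP replicate 2 (camera p = 0.0247). Of 18 YAP/TAZ-TEAD targets, 0 were higher and 3 lower, Ccn1, F3 and Gadd45b, the list did not pass (camera adjusted p = 0.327), and none of the 3 passed once any 1 of the libraries labelled shYAP was left out. Ccn1 had -0.92 ± 0.30 and from -0.996 to -0.84 in those fits, F3 from -1.08 to -0.86 and Gadd45b from -2.001 to -1.63, and Ccn2 had 0.43 ± 0.28 (adjusted p = 0.344). Against shControl replicates 8 to 10 alone Ccn2 was higher and passed (0.80, adjusted p = 0.0306).

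Of 25 cholesterol synthesis genes 17 were lower in the libraries labelled shYAP and 1 higher, including Insig1 (-1.42 ± 0.20), Dhcr7 (-1.39 ± 0.25) and Lss (-1.31 ± 0.21), and of 18 fatty acid synthesis genes 4 were lower, including Acss2 (-2.63 ± 0.42) and Scd1 (-1.38 ± 0.27), and 1 higher. Of 22 hypoxia and glycolysis genes 8 were lower and 0 higher, with Vegfa at -1.47 ± 0.27 and Ndrg1 at -1.27 ± 0.16. All 3 lists passed camera and were lost at adjusted p = 0.237 with an estimated correlation. Endoplasmic reticulum chaperones rose, 10 of 19 with 0 lower, Creld2 by 1.72 ± 0.24 and Calr by 0.98 ± 0.18, and this call too (adjusted p = 9.98e-06) was lost at adjusted p = 0.237 with an estimated correlation. Of 24 genes of G2 and mitosis 9 were lower, Ccnb2 at -0.98 ± 0.17, and that call was lost at adjusted p = 0.276 with an estimated correlation. Of 18 crypt-base stem cell genes 5 were lower, of 9 goblet cell genes 3 and of 6 Paneth genes 2, each with 0 higher and most not passing, with Smoc2 at -4.61 ± 0.92, Reg4 at -2.55 ± 0.43 and Klk1 at -3.04 ± 0.59. Lgr5 had -1.84 ± 0.44 (adjusted p = 0.00951), and did not pass without shYAP replicate 1 (-1.78) or replicate 2 (-1.70). The crypt-base stem cell and Paneth lists were lost at adjusted p = 0.154 with an estimated correlation, and the goblet list's call (adjusted p = 0.0107) at adjusted p = 0.237 with an estimated correlation. The mesenchymal gene Vim (-2.26 ± 0.28) was lower in a list of 3 tested genes, whose call was lost at adjusted p = 0.154 with an estimated correlation. NF-kappaB and inflammatory genes had 4 of 13 higher and 0 lower, and Wnt/beta-catenin targets 4 of 17 lower and 2 higher. Their calls were lost at adjusted p = 0.237 with an estimated correlation and adjusted p = 0.393 with an estimated correlation, and both without shYAP replicate 2 (camera p = 0.0250 and 0.0379), the second also without replicate 3 (camera p = 0.0330).

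Leaving out 1 of the 3 libraries labelled shYAP brought the count from 1261 to between 412 and 515. Against shControl replicates 8 to 10 alone, the libraries with neighbouring numbers, 2229 genes passed, of which 932 were among the 1261 with the same sign. Limma called 1168 genes, 766 higher and 402 lower, and 237 with the run of libraries as a random block, 163 higher and 74 lower. With that block Acss2 (-2.49), Alb (-4.21), Bex1 (-4.92), Dhcr7 (-1.42) and Prox1 (-4.88) had fold changes near those above without passing, and Klk1 (-2.76), Smoc2 (-4.46), Lgr5 (-1.57), Ccn1 (-0.83), F3 (-0.91) and Gadd45b (-1.54) passed neither with it nor without it.

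The difference between the knockout effect and the effect in the libraries labelled shYAP was tested in 1 fit of all 34 libraries, and 2253 of 11960 genes passed, 1177 higher and 1076 lower in the knockout. Clu (-3.46 ± 0.42, edgeR adjusted p = 7.39e-08) and Spp1 (-2.11 ± 0.27) differed among the revival genes, with 11 of 22 lower and 1 higher, and the chaperones Creld2 (-2.59 ± 0.32) and Hspa5 (-1.86 ± 0.24) with 11 of 20 lower and 0 higher. The revival list's call was lost at adjusted p = 0.0847 with an estimated correlation, and that of the chaperones at adjusted p = 0.0632 with an estimated correlation. Cholesterol synthesis differed upward, 14 of 25 with 0 lower, Insig1 by 2.04 ± 0.29 and Cyp51 by 1.61 ± 0.23, with a call lost at adjusted p = 0.216 with an estimated correlation. Slc25a4 (4.83 ± 0.34) and the muscle gene Smpx (5.57 ± 1.19) differed upward, and Ociad2 (-5.09 ± 0.45), Icam1 (-3.75 ± 0.51), Mgat4c (-3.61 ± 0.48) and Ccn2 (-2.03 ± 0.36) downward. Across 10884 genes, the fold changes of the 2 experiments had Pearson r = -0.107 and Spearman rho = -0.125, where genes are not independent replicates. Of 100 splits of the hairpin libraries, 43 gave an r as large in size, and r was 0.111 against shControl replicates 8 to 10 alone. Of the 316 genes higher in both clones and tested in both fits, 25 were higher and 31 lower in the libraries labelled shYAP, where independent lists would share 17.2 and 18.4. Of the 339 lower in both clones, 43 were higher and 35 lower, where independent lists would share 18.4 and 19.8, so the excess ran both ways.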

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

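The tests of an exchange with 3 shControl libraries, of the control libraries' level, of the rise of keratinocyte genes over Scrambled and of an extra chromosome 18 were chosen after the result was seen. The predictions of the others were written before their test was run. Among these, the tests by run and on the hair-type keratins used runs and a gene set that were themselves chosen after their values were seen.

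Single libraries far from the rest of their group appeared in 11 of 300 groups of values tested, where chance gives about 1 in 20. In shControl replicate 3, Cenpe stood at 267 CPM against 127 in the next library, and Mmp7 at 16.4 CPM. Clone1 replicate 2 held 883253 counts, and its Pid1 (9.95 CPM), Myof (114), Cenpe (259), Vegfa (105.0) and Aurkb (11.1) stood apart from the other clone1 libraries. In clone2, Krt31 in replicate 1 (8.48 CPM), Pla2g2a in replicate 6 (1.02) and Zfp422 in replicate 5 (8.25) stood apart. The libraries that recur, clone1 replicate 2 and shControl replicate 3, were the 2 shallowest of all 34.

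The clones differed by the test of clone2 against clone1 in 5649 genes. Genes lower in clone2 were Cyp2c55 (-6.14), Ugt2b34 (-5.28), Otop1 (-5.07), Tm4sf20 (-5.05), Abcb1a (-4.79), Muc13 (-4.20), Krt20 (-3.73), Muc3 (-3.66), Car9 (-3.35), Lgr5 (-3.27), Crim1 (-3.14), Ccn2 (-2.23), Gata6 (-1.82), Cdx2 (-1.55), Mcm7 (-1.54) and Krt8 (-1.51). Genes higher in clone2 were Pex5l (5.75), Hspb8 (5.46), Hoxb7 (4.86), Sprr2a1 (4.72), Samt1b (4.67) and Apcdd1 (3.18). By list, the medians were -4.73 for immune cell genes (3 tested, S100a8 among them), -3.18 for absorptive colonocyte genes, -0.79 for S phase, -0.55 for G2 and mitosis, -0.54 for YAP/TAZ-TEAD targets, -0.35 for crypt-base stem cell genes, -0.27 for epithelial identity and -0.13 for oxidative stress and NRF2 targets. Wnt/beta-catenin targets (0.65) and cytosolic ribosomal proteins (0.31) had medians above 0, and 0 of these lists passed with an estimated correlation. Ribosomal genes have many pseudogenes, so their assignment is uncertain.

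The knockout effect and the effect in the libraries labelled shYAP, whose Yap1 mRNA was not lower, differed in 2253 genes by the interaction test. Lower in the knockout were Ociad2 (-5.09), Icam1 (-3.75), Mgat4c (-3.61), Clu (-3.46), Degs1 (-3.33), Creld2 (-2.59), Spp1 (-2.11), Ccn2 (-2.03), Hspa5 (-1.86) and Ly6a (-0.63). Ly6a did not pass without Scrambled replicate 2 (-0.52) or without shYAP replicate 1 (-0.59) or 2 (-0.58). Higher in the knockout were Smpx (5.57), Slc25a4 (4.83), Insig1 (2.04), Cyp51 (1.61) and Vegfa (1.55). Against shControl replicates 8 to 10 alone Vegfa had 0.81 and did not pass (adjusted p = 0.111), and Smpx did not pass with the replicate number as a block (4.73). List medians were -0.97 for endoplasmic reticulum chaperones, -0.65 for revival and fetal-like genes, -0.63 for S phase, 0.72 for Wnt/beta-catenin targets, 0.67 for cholesterol synthesis, 0.58 for hypoxia and glycolysis and 0.57 for mitochondrially encoded mRNA. With an estimated correlation 0 of these 7 lists passed. The mitochondrial list did not pass without shYAP replicate 3 (camera p = 0.0119), nor S phase (0.777), hypoxia (0.327) and Wnt/beta-catenin targets (0.0488) against shControl replicates 8 to 10, nor the latter with the replicate number as a block (0.0329).

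Of 100 splits of the libraries into groups of the same sizes, 1, the real split, gave as many genes in each of the 7 counts. That would exclude chance only if single libraries were exchangeable, which the runs below speak against. Other splits also mix the lines, which widens the spread within groups and lowers their counts, so they cannot settle the question. The real count and the highest other were 2027 and 2 for the equal-weight knockout effect, 1459 and 317 for clone1, 3810 and 147 for clone2, 678 and 0 for both clones, 5649 and 0 between clones, 1261 and 378 for the libraries labelled shYAP, and 2253 and 23 for the difference of effects. For the correlation of both experiments, 43 of 100 splits gave an r as large in size as the real value of -0.107, so chance cannot be excluded. The other splits ran from -0.301 to 0.196. Splits along the runs gave many genes within a group: 858 for shControl replicates 8 to 10 against the rest, 960 for replicates 1 to 4 against the rest, 992 for clone1 replicates 7 to 9 and 536 for clone2 replicates 7 to 9 against replicates 1 to 6. These point to a structure of the samples within groups, and chance between runs was not excluded by the drawn splits. With the run as a random block, limma called 237 genes for the libraries labelled shYAP and 497 for clone1, and without it 1168 and 1512.

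The first pattern weighed was that the clones differed from each other in more genes than either did from Scrambled. Each clone had 9 libraries and Scrambled 3, so these counts are not on equal terms. With replicates 7 to 9 alone, 4748 genes differed between clones and 4183 in clone2 against Scrambled. The 4748 genes between clones within replicates 7 to 9 lay far above the 992 of the largest contrast between runs inside a clone. Run differences of the size seen inside a clone thus do not account for them. No run held both clones, however, so an effect of runs between clones cannot be told apart from the clones. Shifts of whole chromosomes do not account for most of the genes called between clones. Chromosome 18 alone was shifted by at least 0.3 and held 3.17% of the calls. Centring every chromosome, including 4 and 9 with medians of 0.21 and 0.22, ended 14.3% of them. Whole-chromosome medians cannot show changes of part of a chromosome or effects on genes elsewhere, so copy number was not excluded. For chromosome 18 itself, an extra copy in clone2 is a candidate explanation: its genes had a median of 0.54 against Scrambled, near the 0.58 of 3 copies over 2, in all 9 segments and at 0.45 to 0.59 in every clone2 library. A biological difference between the clonal lines stays open and was not tested, since the design has no second line per edit.

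The second pattern was that Yap1 mRNA was not lower in the libraries labelled shYAP. Too few reads do not explain it, since the 95% interval of the log2 change ended at -0.30 and left no room for a loss of 1. The choice of shControl run does not explain it either, since the change was 0.0774 ± 0.202 against shControl replicates 8 to 10. The libraries labelled shYAP formed 1 run of their own, so an effect of that run on Yap1 was not tested. That 0 of 13 libraries sat nearest the other group does not decide on swapped labels alone, since 2 of 120 exchanges with 3 shControl libraries, replicates 5 to 7 or 8 to 10, would leave it so, but the changes of -0.0648 ± 0.217 and 0.0774 ± 0.202 against these left no room for a lower Yap1 there by 1. A wrong label against an outside sample, and a hairpin acting on protein without lowering mRNA, stay open and were not tested.

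The third pattern was that 11 of 11 hair-type keratins tested were higher in both clones than in Scrambled, though against shControl 3 were higher in clone1, 9 in clone2 and 2 in both. Keratinocyte genes changed by -3.24 CPM from Scrambled, to 22.4 ± 9.42 in clone1 and 18.6 ± 2.91 in clone2 from 23.7 ± 1.01. The keratins rose by 321 CPM, so cells that carry these keratinocyte genes do not account for the rise. The share of the keratinocyte genes in these keratins, 7.12% over both clones, was 10.3% in clone1 and 3.93% in clone2. It did not by itself stay under the tenth set before. Cells that make hair-type keratins without these keratinocyte genes were not tested and stay open. Shared reads between paralogs stay open. The other keratin and keratin-associated genes together changed by 759 CPM (SD 570 over the knockout libraries), without the fall that had been looked for. That sum cannot decide the question, since keratin reads can spill over without such a fall. It also held keratin-associated genes, another family, of which Krtap3-3 and Krtap3-1 rose in both clones. Copy number would raise the 52 neighbouring genes, whose median was 0.13. In clone1 the level of the control libraries may be the explanation, since only 3 of 9 clone1 libraries lay above the highest of the 13 control libraries, at 264.5 CPM, and shControl ran from 17.0 to 41.8 CPM in replicates 1 to 4 and from 234.5 to 264.5 in replicates 5 to 7. In clone2 all 9 lay above it, so that level does not account for clone2. There shared reads, cells without the tested keratinocyte genes, loss of Degs1 and clonal drift all stay open.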

How the results depend on the processing

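Every alternative changed 1 choice at a time, except that DESeq2 brought its own size factors and limma with the run as a random block changed test and block together, and none of the alternatives fixed in advance was left out. For single genes, 1985 values kept their side of the threshold, 99 kept their direction but no longer passed, 9 newly passed and 1 reversed. The 1985 include values past the threshold in neither fit, whether or not their sign changed. Of the values for gene lists that had passed in the main fits, 579 kept direction and side, 121 no longer passed and 4 reversed. Lists that had not passed there were left out of this tally, so it cannot show lists that newly passed. Size factors, no filter on low counts, DESeq2, only the compared groups in a fit, the replicate number as a block and leaving out the shallowest library kept every count of genes within 1.5 times. With the replicate number as a block, however, 1730 genes passed for the libraries labelled shYAP, and only 863 of the 1261 were among them with the same sign. That block sets these libraries against the shControl replicates of the same numbers alone. Without each Scrambled replicate in turn, 1208 to 1374 genes passed for the equal-weight knockout effect, 779 to 1025 for clone1 and 359 to 481 for both clones, and without each replicate labelled shYAP 412 to 515 passed in the hairpin experiment. A threshold of 0.01 left 1184, 756, 453, 1161 and 333 genes for the equal-weight effect, clone1, the libraries labelled shYAP, the difference of effects and both clones. In 1 fit of all 5 groups, 2065 genes passed for the libraries labelled shYAP, and 2604 against shControl libraries 201013 to 201016 alone, and the cause was not tested. The remaining alternatives were chosen after seeing the data. Against shControl replicates 8 to 10 alone, 2229 genes passed for the libraries labelled shYAP and 1423 for the difference of effects, and the correlation of both experiments was 0.111 in place of -0.107. Knockout replicates 1 to 6 alone gave 1048 genes in both clones. With the run as a random block, limma called 1063 for the equal-weight effect, 497 for clone1, 2522 for clone2, 237 for the libraries labelled shYAP and 241 for both clones, with an estimated correlation within runs of 0.258 and 0.335 in the 2 experiments. Limma without that block called 2192, 1512, 4067, 1168 and 709 for these, so the fall came with the block. Camera with an estimated correlation left 3 of 9 lists for the equal-weight effect, 1 of 10 for clone1, 3 of 11 for clone2, 0 of 10 between clones, 1 of 13 for the libraries labelled shYAP and 0 of 7 for the difference, since the estimated correlation exceeded the preset one for most lists. With shControl in place of Scrambled, 2376, 2154 and 4170 genes passed for the equal-weight effect, clone1 and clone2, of which 972, 769 and 2566 were those of the comparison with Scrambled with the same sign. There the direction reversed for Lgr5 in clone1 (0.58), for the crypt-base stem cell list (camera p = 0.118) and mitochondrially encoded mRNA (camera p = 0.775) in clone1 and for Wnt/beta-catenin targets in clone2 (camera p = 0.828), so these rest on the Scrambled line. With knockout replicates 7 to 9 alone the S phase list reversed in clone1 (camera p = 0.0140), and the cause was not tested. Depth limits clone1 replicate 2 above all, at 883253 counts.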

Other observations

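Several genes were close to lost in a single line. Fundc2, a mitophagy-related gene of the X chromosome, averaged 9.63 ± 2.31 CPM in clone1 (n = 9) and at least 90.1 in the mean of every other group, and Hoxb7 0.687 ± 0.40 CPM in clone1 against 16.5 or more. Abcb1a averaged 4.24 ± 1.78 CPM in clone2 and 32.8 or more elsewhere. Slc25a4 at 3.10 ± 0.798 CPM in the libraries labelled shYAP stood against 36.8 or more elsewhere. Ociad2, chosen here after its values were seen, averaged 1.89 ± 1.08 CPM in clone1 and 1.22 ± 0.442 in clone2, against 25.1 ± 5.60 in Scrambled. The differentiation-linked gene Dapl1 averaged 2066 ± 439 CPM in clone2, 312 ± 162 in clone1 and 321 ± 103 in shControl, and 59.6 ± 6.20 in Scrambled, which was the lowest of the 5 groups. Krt15 was above the control libraries in both clones, at 12.2 to 41.2 CPM against at most 6.38.

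Lists not yet given for the equal-weight knockout effect did not pass camera. Immediate early genes had 7 of 22 higher and 2 lower, interferon response 3 of 16 higher and 2 lower, antigen presentation 3 of 7 higher and 1 lower, fatty acid oxidation 4 of 18 higher and 1 lower, fatty acid synthesis 2 of 18 higher and 2 lower, p53 targets 2 of 16 higher and 1 lower, and cytosolic ribosomal proteins 1 of 42 higher and 9 lower. Fibroblast, immune and endothelial lists had 1, 3 and 1 genes tested.

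The control lines differed from each other in 191 of 11247 genes, 99 higher and 92 lower in Scrambled than in shControl. This set 3 libraries against a shControl group whose own runs differed in 858 or 960 genes, so the low count does not show that the lines are alike. With shControl in place of Scrambled, 972 of the 2027 genes of the equal-weight knockout effect passed with the same sign. Lgr5 averaged 23.1 ± 3.80 CPM in Scrambled and 7.62 ± 3.41 in shControl. Car9 averaged 124 ± 4.24 in Scrambled and 59.6 ± 28.7 in shControl, and both clones lay below either, at 13.5 ± 3.57 and 1.36 ± 0.809. The libraries labelled shYAP lay at 11.1 to 13.5 CPM, at the level of clone1, so low Car9 was not particular to the knockout. The series draws both experiments from organoids of 1 genotype, but whether both control lines share a parent culture was not stated.

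Smaller shifts by chromosome, chosen after their values were seen, were present in clone1. Genes of chromosome 4 had a median of -0.27 against Scrambled and were lower in all 16 segments, and those of chromosome 9 had -0.24 and were lower in all 13. Chromosome 1, which carries Degs1, had a clone1 median of -0.18, with 16 of 19 segments lower. Its median was -0.20 to -0.13 over the clone1 libraries. In clone2, chromosome 15 stood at 0.26 to 0.29 in replicates 7 to 9 and at 0.02 to 0.10 in replicates 1 to 6, so libraries of 1 clone were not uniform. Whether a part of the cells carried another copy number was not tested.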
